A study of Caenorhabditis elegans with 4 samples.

How the data were processed

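Binding of RNA polymerase II (Pol II) was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in fed first-stage (L1) larvae of the wild-type *Caenorhabditis elegans* strain N2. The labels list 4 samples, 2 of Pol II ChIP DNA and 2 of input DNA, numbered as replicates 1 and 2. Per the labels' protocols, synchronized larvae were grown at 20 °C on the bacterium HB101 and crosslinked with 2% formaldehyde. The labels name the mouse monoclonal antibody 8WG16, which recognizes the heptapeptide repeat at the C-terminus of the largest Pol II subunit. The protocol text attached to all 4 samples is a general one that speaks of embryos and of an anti-GFP serum, so it differs from the labels in stage and antibody. The labels are followed here.

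The authors deposited a single list of binding sites for the series, whose name says that it is combined. Per the file headers, its coordinates are those of the WormBase WS180 build, and per its source field the sites were called by PeakSeq. Each line gives a chromosome, a start, an end and the q-value deposited by the authors for ChIP against input. The q-value stands in the score field and again in the attribute field, and both were identical in every line. The highest q-value was 0.00996, just under 0.01. The aligner, the caller's version, the handling of replicates and the read depth are not given in the sources used here. The depth behind each site is therefore unknown, and no interval that needs it is given. The list holds no read count, no fold enrichment and no value for a single library, so no error between replicates could be computed. A q-value measures how surely a site was called. It grows smaller with the width and depth of a site as well as with its enrichment, so it is used here only to rank sites within this list.

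Sites were ranked by q-value, which had 1967 distinct values. In the order of the file, 338 lines had a q-value below that of the line before, by a factor of at most 1.0024. The span of a chromosome was taken from the start of its first site to the end of its last site, since chromosome lengths of the WS180 build were not used here. Densities are sites per Mb of that span. Covered bases are the summed widths of the sites, which did not overlap. The relation of width to q-value was tested with Spearman's rho and 100000 permutations. Positions along a chromosome were tested by counting site midpoints in the middle of 3 equal parts of the span, against 10000 rotations of all sites of a chromosome by a random distance, which keep the clustering of sites. Widths at matched rank were compared within 10 bins of equal size by rank. The statistic was the difference of mean log2 width between a chromosome and the others, averaged over bins with the chromosome's site numbers as weights, and given as a ratio. The chromosome label was permuted 10000 times within bins, and the 11 such tests were adjusted by the Benjamini-Hochberg method. Unlike the rotations, this permutation does not keep the clustering of sites, so its p may be too small. Shares were compared with Fisher's exact test, which does not keep the clustering either, so its p may also be too small. All tests are two-sided. They treat sites of 1 list as units, and sites are not replicates, so a p describes this list and not the spread between cultures. The position test, the matched width test and the share tests were chosen after the data were seen.

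The rule for the sites named was fixed before the data were examined: the 10 sites with the lowest q-values and the 5 widest. Dense windows, gaps and the sites in the closing section were chosen after their values were seen. The plan also held an assignment of sites to genes, gene starts, gene lists and RNA classes. It was not run, because the gene table at hand belongs to the WBcel235 assembly and coordinates of different builds cannot be mixed. No gene is therefore named.

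The alternatives were the 983 sites with the lowest q-values alone, the joining of sites less than 500 bp apart, and covered bases in place of site numbers. Joining over gaps under 10 kb, leaving out chromosome I, and joining at 500 bp for the percentages of sites per chromosome and for the tests of position and width were added after the data were seen. The procedures were tested on simulated data with the real number of 1967 sites. With evenly placed sites, 6% of 100 simulations passed 0.05 in the position test, and with 60% of sites placed in the middle part the mean share found was 60.0%. Simulated sites were placed independently of each other, and all chromosomes were tested together. The position test was therefore not checked on clustered sites or on the autosomes alone. With shuffled chromosome labels, 6% of 100 simulations passed 0.05 in the matched width test, and a true ratio of 0.5 was found as 0.50. The test itself permutes these labels, so such a rate was set in advance. It does not check the test on neighbouring sites with correlated widths. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.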

Results

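The data describe where RNA polymerase II was bound in whole fed L1 larvae of the wild-type strain N2, the laboratory reference strain of *C. elegans*. The samples are 2 of ChIP DNA and 2 of input DNA, where input is crosslinked chromatin that was not immunoprecipitated. The only comparison in the design is ChIP against input, and its result is the authors' combined list of binding sites on the WS180 build. No value per replicate was available, so no value below carries an error between replicates. Sequencing depth is unknown.

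Pol II was called at 1967 binding sites that lay on all 6 nuclear chromosomes. Together the sites covered 2.96 Mb, or 3.02% of the 98.2 Mb between the first and last sites of the chromosomes. The median site was 770 bp wide, with an interquartile range of 384 to 2003 bp. The widest reached 15.2 kb. There were 109 sites of at least 5 kb and 10 of at least 10 kb. At the other end, 60 sites were under 50 bp and 6 were a single base. The authors' q-values ran from 2.69e-286 to 0.00996 with a median of 1.21e-05. A q-value below 1e-50 was given to 147 sites, and 64 sites were below 1e-100.

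The strongest site by the authors' q-value lay on the X chromosome, from 6735449 to 6750660, with a q-value of 2.69e-286. It was also the widest site of the list, at 15.2 kb. The second strongest was a 3.81 kb site on chromosome I from 7489650 to 7493460, with a q-value of 1.03e-270. A 5.60 kb site on chromosome III from 5501257 to 5506856 (q = 1.67e-262) and a 5.64 kb site on X from 6252000 to 6257638 (q = 4.42e-262) came next. They were followed by a 4.62 kb site on chromosome V from 14684572 to 14689189, with a q-value of 3.35e-253. Ranks 6 to 10 were held by sites on chromosome I (8133343 to 8136919), chromosome III (8443206 to 8447259), chromosome IV (16166513 to 16171692), chromosome V (5838522 to 5847065) and chromosome IV (4467987 to 4474498). Their q-values lay between 2.28e-243 and 1.77e-218, and their widths between 3.58 and 8.54 kb. All 10 were at least 3.58 kb wide, against a median of 770 bp for the whole list. Which genes these sites cover was not analysed here.

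The other 4 of the 5 widest sites differed in strength. On chromosome IV, the site from 14610877 to 14624610 spanned 13.7 kb and ranked 227th, with a q-value of 1.15e-32. On chromosome III, the site from 345418 to 358076 spanned 12.7 kb with a q-value of 1.19e-21, and the site from 4496958 to 4508689 spanned 11.7 kb with a q-value of 1.22e-11. On chromosome I, the site from 6573701 to 6585987 spanned 12.3 kb with a q-value of 1.37e-144. Across all sites, wider sites had lower q-values: Spearman's rho of width with −log10 q was 0.66 (1967 sites, permutation p = 1e-05, the smallest that 100000 permutations can give). A q-value grows smaller with the width of a site, so a positive rho was expected in advance and its p adds little. The relation was across sites, which are not independent replicates. It held on chromosome I alone (rho 0.69, 861 sites) and on the other chromosomes (rho 0.66, 1106 sites), each with the same permutation p of 1e-05. The 983 sites with the lowest q-values held 77.3% of all covered bases.

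**Figure D1:**
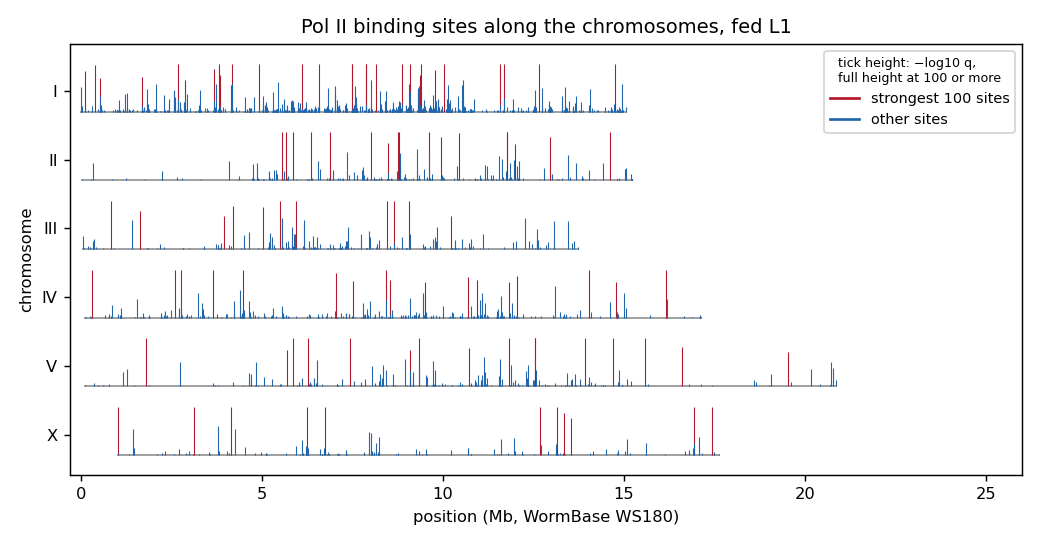
Positions of the 1967 binding sites on the 6 chromosomes, in Mb of the WS180 build. Each tick is a site, its height is −log10 of the authors' q-value and is cut at 100, red ticks are the 100 strongest sites, and the grey line runs from the first to the last site. Chromosome I has sites along its whole span, with 24 to 112 in each whole megabase, and it holds 28 of the 100 strongest sites.

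The chromosomes differed widely in the number of sites. Chromosome I held 861 of the 1967 sites, or 43.8%, on 15.3% of the total span. Its density was 57.3 sites per Mb, against 18.3 on chromosome IV, 15.2 on each of chromosomes II and III, 10.5 on chromosome V and 8.30 on X, whose span starts at its first site at 1010457. The excess was smaller when sites under 10 kb apart were joined: chromosome I then had 28.7% of the sites and 19.9 sites per Mb, against 11.6 on chromosome IV. Covered bases differed less: sites covered 5.04% of the span of chromosome I, 3.33% of III, 3.12% of IV, 2.58% of II, 2.36% of V and 2.03% of X. In bases, chromosome I thus held 25.6% of the total and X 11.4%, whereas X held 7.02% of the sites. With no value per replicate, these differences cannot be set against the spread between replicates.

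The excess on chromosome I was smaller among the strongest sites. Of the 100 strongest sites, 28 lay on chromosome I, 17 each on II and IV, 16 on V, and 11 each on III and X. Among the remaining 1867 sites the share of chromosome I was 44.6% (Fisher's exact p = 0.0012 for 28% against 44.6%). Of the 50 strongest sites, 12 lay on chromosome I, 11 on V and 7 on X. Sites of chromosome I were also the narrowest, with a median of 498 bp. The medians were 970 bp on II, 1077 bp on IV, 1259 bp on III, 1491 bp on V and 1661 bp on X. Of the 60 sites under 50 bp, 34 lay on chromosome I, as did 122 of the 189 sites under 200 bp and 17 of the 109 sites of at least 5 kb. Neighbouring sites were closest on chromosome I, with a median gap of 3.09 kb against 21.0 to 55.9 kb on the other chromosomes.

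**Figure D2:**
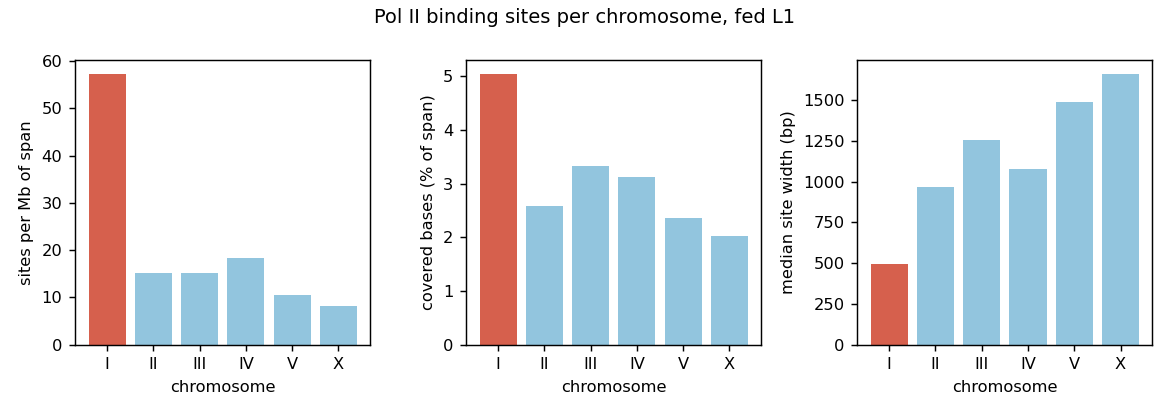
Sites per Mb, covered bases in percent of the span and median site width in bp for each chromosome, with chromosome I in red. Chromosome I had 57.3 sites per Mb and a median width of 498 bp, and X had 8.30 sites per Mb and a median width of 1661 bp.

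Width was then compared between sites of like rank, with a permutation that does not keep the clustering of neighbouring sites. Sites of chromosome I were 0.51 times as wide as those of the other chromosomes at matched rank (861 sites, permutation p = 0.0001, the smallest that 10000 permutations can give, adjusted p = 0.000275). This ratio is an average over bins, and the difference was not uniform. In the strongest bin the median width was 3577 bp on chromosome I against 4041 bp on the others. It was 953 against 2387.5 bp in the third bin and 311.5 against 441 bp in the ninth. Sites of X were 1.75 times as wide as all others at matched rank (138 sites, permutation p = 0.0001, adjusted p = 0.000275). With chromosome I left out, X sites remained wider than those of chromosomes II to V, at 1.31 times (permutation p = 0.0042, adjusted p = 0.0066). Against the other chromosomes without I, the ratios were 0.90 for II, 0.99 for III, 0.99 for IV and 0.95 for V, and none of these 4 passed the test (adjusted p of 0.27 or more). When sites under 10 kb apart were joined, neither the ratio for I (1.07, permutation p = 0.43) nor that for X (1.17, permutation p = 0.23) passed the test. Joined widths include the gaps, and more sites were joined on chromosome I (861 to 299) than on X (138 to 100).

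**Figure D3:**
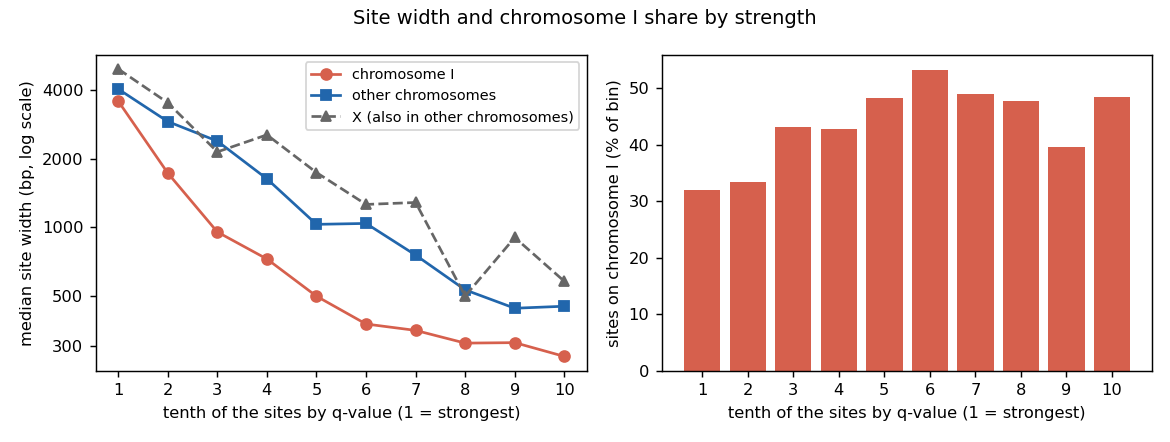
Left, median site width in bp (log scale) in 10 bins of the sites by q-value, from the strongest to the weakest, for chromosome I, for the 5 other chromosomes and for X alone. Right, the percentage of each bin on chromosome I. Chromosome I sites were narrower in every bin, and their share was 32.0% in the strongest bin, 53.3% in the sixth, and 49.0%, 47.7%, 39.6% and 48.5% in the last 4 bins.

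Along the autosomes, Pol II sites were concentrated in the middle. In *C. elegans* the autosome centres are known to be gene-rich and the arms repeat-rich, while X is more even. The middle of 3 equal parts of the span held 955 of 1829 autosomal sites, or 52.2%, against 33.4% ± 6.15 (mean and SD of 10000 rotations, permutation p by rotation = 0.0004). Without chromosome I the share was 52.0% of 968 sites (permutation p by rotation = 0.0058). The share was 52.5% on I, 50.6% on II, 53.4% on III, 45.0% on IV and 61.9% on V. Taken singly, chromosome I had an unadjusted permutation p of 0.040, and the other 4 autosomes had p from 0.071 to 0.38, so none of these 4 passed 0.05. Rotations of these 4 chromosomes varied widely (SD from 10.7 points on IV to 18.0 on V). A p above 0.05 therefore does not show that their sites were evenly spread. On X the middle part held 37.7% of 138 sites (permutation p by rotation = 0.60). The span of X began at its first site, at 1010457, against 122839 or less on the autosomes. Where the middle part of X lies, and so its share, depends on that choice, and no other span was tried. The difference of 14.5 percentage points between autosomes and X was not larger than rotations gave (SD 8.91 points, permutation p = 0.11).

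The densest megabase of each autosome overlapped this middle part. On chromosome I the megabase from 9000001 to 10000000 held 112 sites, and no whole megabase of that chromosome held fewer than 24. The densest megabases of the other autosomes held 36 sites on II (8000001 to 9000000), 31 on III (5000001 to 6000000), 37 on IV (11000001 to 12000000) and 27 on V (9000001 to 10000000). On X the megabase from 6000001 to 7000000 held 20 sites, the strongest site of the list among them, and the first megabase of X was the only whole megabase counted that held no site. By covered bases, the densest 100 kb window was on chromosome I from 9300001 to 9400000, where 17 sites covered 21.1%. It was followed by chromosome IV from 4400001 to 4500000, where 8 sites covered 20.3%. Of the 20 windows with the most covered bases, 8 were on I, 4 each on III and IV, 2 on X and 1 each on II and V. The longest stretch between neighbouring sites was 1.15 Mb on the right arm of chromosome V, from 17421679 to 18572768. The longest such stretch on chromosome I was 0.285 Mb.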

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

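Joining at 10 kb, leaving out chromosome I, joining at 500 bp for the percentages per chromosome, and all tests of position and of width at matched rank were chosen after the data were seen. Of 32 alternative values of 8 results, 16 held (same direction and side of the threshold for a test, within 1.5 times for the number of sites, within the 95% interval for other values), 15 moved or no longer passed the test, and 1 reversed. Some values had to move: the number of sites when sites were left out, and the percentage on X without chromosome I. Covered bases are another quantity than site numbers. The tally is therefore not a measure of robustness. The 1967 sites became 983 when only those with the lowest q-values were kept, 1677 and 1043 when sites under 500 bp and under 10 kb apart were joined, and 1106 without chromosome I. The median width of 770 bp became 1583 bp, 878 bp, 2609 bp and 1231 bp under the same changes. The percentage of sites on chromosome I was 43.8 as listed, 40.0 among the lowest q-values, 40.1 after joining at 500 bp, 28.7 after joining at 10 kb, and 25.6 by covered bases. The percentage on X was 7.02 as listed, 9.59 after joining at 10 kb, 12.5 without chromosome I and 11.4 by covered bases. Joining at 10 kb reversed the width ratio of chromosome I from 0.51 to 1.07 and lowered that of X from 1.75 to 1.17, and neither then passed the test. Joined widths include the gaps, and chromosome I went from 861 to 299 sites and X from 138 to 100, so these ratios also reflect the density of sites. The rank correlation of width with q-value and the share of autosomal sites in the middle part passed their tests under all 4 alternatives run for each. For the correlation this was expected in advance, since a q-value depends on width. Analyses by gene, gene start and gene list, with their alternatives, were not run for want of an annotation of the WS180 build. No paired analysis was possible because the list holds no value for a single replicate. Unknown depth limits every statement on weak sites.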

Other observations

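Strong sites were of various shapes. Among the 50 strongest, the 5 narrowest were all on chromosome II or V. Chromosome II had sites of 822 bp (5844542 to 5845363, q = 2.74e-124), 836 bp (11761567 to 11762402, q = 4.87e-141), 970 bp (11756278 to 11757247, q = 2.52e-156) and 1159 bp (5543296 to 5544454, q = 3.18e-199). Chromosome V had 2 neighbouring strong sites of 2003 bp (12548575 to 12550577, q = 7.65e-153) and 2509 bp (12551247 to 12553755, q = 4.43e-176). At the other extreme, 20 sites of at least 5 kb lay outside the 491 strongest. The widest of these were on chromosome III (4496958 to 4508689, 11.7 kb, q = 1.22e-11; 10810530 to 10821024, 10.5 kb, q = 6.43e-08) and on chromosome V (16777566 to 16787186, 9.62 kb, q = 1.70e-06). These sites were chosen after their values were seen.

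All tests in this part were chosen after the data were seen. Chromosome I carried more and narrower sites than any other chromosome. A few dense clusters cannot account for the number, since its median whole megabase held 46 sites against at most 18 on the others. Splitting of the same regions into more pieces cannot account for all of the number, since after joining over 10 kb chromosome I kept 19.9 sites per Mb against at most 11.6. A lower detection limit on chromosome I, such as more ChIP reads or a lower scaled input there, stays open. Shares by strength cannot decide it, since more reads or a lower scaled input would lower the q-values of strong sites too. Chromosome I held 28% of the strongest 100 sites against 44.6% of the rest. Wider sites had lower q-values, so narrower sites on chromosome I would be expected to give such a difference too. Its share was 40.0% among the 983 sites with the lowest q-values and 47.6% among the other 984 (Fisher's exact p = 0.000768). Narrower sites would be expected to give this difference too. In single bins by rank the share did not rise steadily toward the weakest sites (53.3% in the sixth bin, 39.6% in the ninth and 48.5% in the last). For the narrower sites (0.51 times as wide at matched rank) splitting at gaps under 500 bp cannot account for all of the difference, since the ratio was 0.56 after such joining (permutation p = 0.0001). Splitting over wider gaps stays open, because joining at 10 kb took chromosome I from 861 to 299 sites and X from 138 to 100, and so adds more gaps to a site where sites are dense. A detection limit was not tested for the widths. No biological explanation was tested, and without read counts per chromosome a true excess of bound loci on chromosome I also stays open.

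X had the fewest sites per Mb. The hypothesis that weak sites in particular were missed on X was tested with chromosome I left out. X held 13.4% of such sites among the lower q-values (79 of 590) and 11.4% among the higher (59 of 516), and Fisher's exact p was 0.36. A p above the threshold does not show equal shares, so detection and occupancy both stay open for the sparse sites of X.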
